A study of Mus musculus with 28 samples.

How the data were processed

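RNA was sequenced from female mouse embryonic stem cells of the line RGd2. The cells were grown in 2i, a medium with an inhibitor of Gsk3 and one of Mek that holds them in the naive state (the stage named ESC), or were taken 16 h or 32 h after 2i was withdrawn, when they leave that state. The genotypes were wild type (WT) and knockout (KO) lines of Zfp281, Ehmt1, Zic2, and Ehmt1 with Zic2 (the double KO). Per the labels' protocols, the Zfp281 KO cells and their WT cells gave ribosome-depleted total RNA libraries (ScriptSeq, 12 libraries, here the ribo-depleted set), and all other genotypes and their WT cells gave mRNA libraries (TruSeq, 16 libraries, here the polyA set).

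The authors deposited raw counts per gene, whole numbers for 24116 Entrez gene IDs, as a table of 24 libraries (ESC and 32 h) and a separate table of 4 libraries (16 h). Per the submitters' processing notes, the genome build was GRCm38 (mm10) and edgeR was used. The aligner, the counting tool, the annotation, the strand setting and any filter are not given in the sources used here. Reads of near-identical genes (Magea and Zscan4 copies, Usp17l genes, ribosomal protein pseudogenes) can be split or dropped in counting, so counts of those families are uncertain, and the same holds for overlapping and antisense genes, since no strand setting is given. All columns were matched to a sample by name, and 0 columns were mapped to no sample. Symbols and coordinates were taken from the RefSeq gene table of GRCm38.p6, in which 24061 IDs had a match and 55 had none. Exonic lengths came from GENCODE vM21.

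The ribo-depleted ESC and 32 h libraries, the ribo-depleted 16 h libraries and the polyA libraries were fitted separately, because the 16 h table was deposited on its own and the kits capture different RNA. In each fit, genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18971, 15139 and 15667 genes. Library sizes were scaled by TMM, and all groups of the fit shared the estimate of the spread. Each comparison was an edgeR quasi-likelihood test with robust dispersion, with p-values adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene or a count of genes in the text comes from this test unless another is named. A difference in the 32 h response is the interaction of genotype with stage, and departure from additivity is the double KO effect minus the sum of both single KO effects. The ± after a log2 fold change is its standard error, obtained as the size of the fold change divided by the square root of the F statistic. Levels are in CPM, counts scaled by the TMM-normalised library size, as mean ± SD, n = 2 libraries per group. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

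Before the data were examined, 22 gene lists with 349 genes were fixed from textbook knowledge; 1 of the genes was not found. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. The count of called members is given over all genes tested and as adjusted over the list alone. Where only the first is given, the second was the same. In no called list test did the median, the mean and the test differ in sign. In the 18 comparisons the preset correlation called 109 list tests and an estimated correlation called 10 without the block. A list not given for a comparison was not called in it. These 10 were the Magea list in the 5 comparisons of Ehmt1 KO or double KO with WT or Zic2 KO cells, and the naive list in the polyA WT time course, in the double KO at 32 h, in the Ehmt1 KO and double KO differences of response, and in the double KO against Ehmt1 KO. All other list calls were lost with the estimated correlation, as were those made only with the line as a block. Its p, adjusted over the lists too, is given as the estimated-correlation p.

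Also fixed before the data were examined were the samples' groups, the tests, the processing alternatives and the rule for named genes. That rule took the targeted genes and Ehmt2. It took up to 6 genes per direction with the largest fold changes among those with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap of libraries between groups, passing over predicted and multi-copy genes. It took up to 5 members of each list with the smallest adjusted p, or up to 2 with the highest CPM where none was called. For the naive, general pluripotency, formative, germline, 2-cell-like and DNA methylation lists any member was allowed as a value, and Xist as a check of X chromosome state. The genes named in the text are a part of the genes this rule allows, picked after their values had been seen and before the alternatives were run on them. Some genes that the rule allows are not reported here. For a gene with no count in a group, a fold is given as a lower limit against a floor of 3 counts over the group. With 1 to 3 counts a ratio between groups is given with its 95% interval, and for a difference in response the count is named instead. Intervals and floors cover counting error only.

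Total counts were 18086421 to 36365192 per library. Common biological coefficients of variation were 0.296, 0.101 and 0.15 in the 3 fits. No replicate pair held identical values, and the chi-square per gene between replicates was 3.57 to 37.4 over genes with at least 20 summed counts, so no pair agreed within sampling noise. KO replicates are separately numbered clones, and WT replicates carry different line names. The labels give no culture days, so the p-values measure the spread between these lines. The test was run on simulated data with 200 changed genes. For Zfp281 KO at 32 h it recovered 82% of 2-fold and 93% of 4-fold changes with 16 false calls among 191, for Zfp281 KO at 16 h 74% and 97% with 24 among 195, for Ehmt1 KO at 32 h 60% and 95% with 12 among 167, and for the Ehmt1 KO difference in response 41% and 81% with 3 among 125. The false share was above the nominal 5% in the first 3. Real groups differ in spread, so these shares hold for the simulation only.

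A line carries the same name at ESC and 32 h, so the stages are paired by cell line. Deviations of the same line from the group means at the 2 stages had a correlation across genes of 0.44 (ribo-depleted WT), 0.28 (Zfp281 KO), 0.08 (polyA WT), 0.67 (Ehmt1 KO), 0.44 (Zic2 KO) and 0.63 (double KO). The main fit had no block. The alternatives were the line as a replicate block, DESeq2's size factors in edgeR, no filter on low counts, DESeq2's Wald test, a fit of only the groups compared, leaving out each library in turn, the 16 h libraries fitted jointly with the other ribo-depleted ones, an estimated correlation in camera, fry, a minimum of 5 CPM in both kits for the correlation between kits, no fold minimum for the transition genes, and a prior count of 0.5 in place of 2 for their response. Chosen after seeing the data were the fits without the WT line named Zfp281_WT, the fits without X-linked genes, list tests with each library left out, estimated correlations with the block, and, in the comparison of KO effects with each other, leaving out single libraries and setting each KO against a different WT library.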

Results

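Gene expression was measured by RNA sequencing in female mouse embryonic stem cells held in the naive state by 2i (ESC) and 16 h or 32 h after 2i was withdrawn, in WT cells and in 4 KO genotypes. The series asks how Zfp281, a zinc finger transcription factor, works with Ehmt1, a histone H3 lysine 9 methyltransferase, and Zic2, another zinc finger transcription factor, as cells move between pluripotent states. The ribo-depleted set held WT and Zfp281 KO cells at ESC, 16 h and 32 h, and the polyA set held WT, Ehmt1 KO, Zic2 KO and Ehmt1/Zic2 double KO cells at ESC and 32 h. Each of the 14 groups had n = 2 libraries, from 2 KO clones or 2 WT lines. The WT lines were named WT (replicate 1) and Zfp281_WT (replicate 2) in the ribo-depleted set, and Ehmt1_WT (replicate 1) and Zic2_WT (replicate 2) in the polyA set. Total counts were 18086421 to 35911590 in the ribo-depleted ESC and 32 h libraries, 28538287 to 36365192 at 16 h, and 19013882 to 28777604 in the polyA libraries.

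The line Zfp281_WT stood apart at ESC and 32 h. Of 1095 olfactory receptor genes, which stem cells do not need, 89.2% (ESC) and 87.0% (32 h) had a count in this line, against 11.1% to 24.7% in the other 6 ribo-depleted libraries of those stages. At 16 h the share was 8.7% to 12.3% in all 4 libraries, this line included. X-linked genes took 3.33% to 3.49% of all counts in Zfp281_WT, 3.94% to 3.98% in WT and 4.4% to 4.8% in the Zfp281 KO clones.

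The targeted genes were read first as a check of the labels. Zfp281 (Entrez 226442, GRCm38 chromosome 1, 136624901 to 136630391) had 238 to 350 CPM in all 12 ribo-depleted libraries. In the libraries labelled Zfp281 KO its log2 fold change against WT was 0.05 ± 0.11 at ESC (adjusted p = 0.78), 0.02 ± 0.08 at 16 h (adjusted p = 0.89) and 0.19 ± 0.11 at 32 h (adjusted p = 0.24). Ehmt1 (77683, chromosome 2, 24790769 to 24919643) was lower in every library labelled Ehmt1 KO or double KO. It had 80.3 and 93.4 CPM in WT at ESC and 149 and 154 CPM at 32 h, against 17.6 to 31.4 CPM in the 4 Ehmt1 KO libraries and 25.4 to 30.5 CPM in the 4 double KO libraries. Its log2 fold change was -2.03 ± 0.17 (Ehmt1 KO, ESC), -2.49 ± 0.17 (Ehmt1 KO, 32 h), -1.76 ± 0.17 (double KO, ESC) and -2.35 ± 0.17 (double KO, 32 h), with adjusted p from 1.2e-06 to 9.9e-06. Zic2 (22772, chromosome 14, 122475384 to 122480328) had 105 and 111 CPM in WT at ESC and 144 and 146 CPM at 32 h. In Zic2 KO clones 1 and 2 it had 107 and 149 CPM at ESC and 156 and 228 CPM at 32 h. Double KO clone 1 had 141 and 208 CPM and double KO clone 2 had 66.5 and 77.3 CPM at ESC and 32 h. The Zic2 log2 fold change was 0.25 ± 0.39 (adjusted p = 0.89) and 0.41 ± 0.39 (adjusted p = 0.84) in Zic2 KO and -0.05 ± 0.39 (adjusted p = 0.93) and -0.02 ± 0.39 (adjusted p = 0.97) in the double KO. The altered part of each gene is not given in the labels, so these counts do not check those labels, and Zfp281 KO, Zic2 KO and double KO stand for the libraries labelled so. Ehmt2 (110147, chromosome 17, 34898463 to 34914073), which encodes the partner of Ehmt1, did not pass the test in any polyA KO group.

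**Figure D1:**
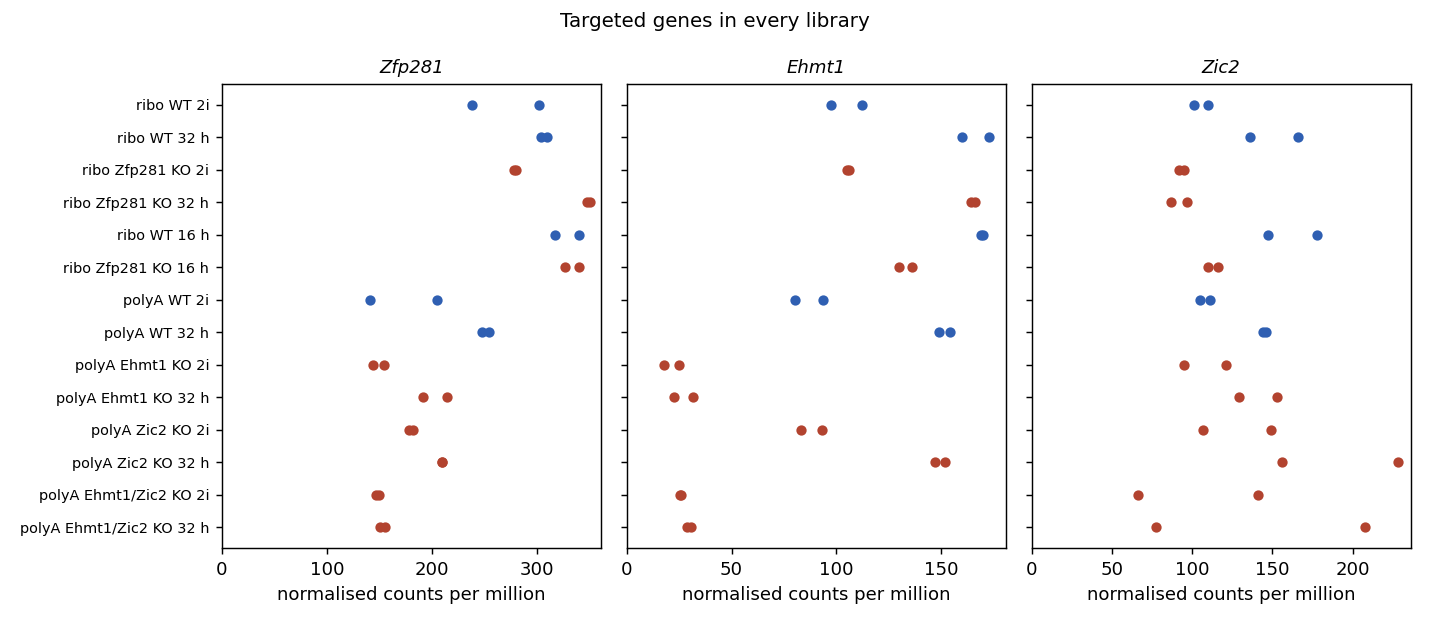
Normalised CPM (x axis, from 0) of Zfp281, Ehmt1 and Zic2 in every library, grouped by kit, genotype and stage, with WT libraries in blue, KO libraries in red and 1 point per library. Ehmt1 is at 17.6 to 31.4 CPM in all Ehmt1 KO and double KO libraries, while Zfp281 stays at 238 to 350 CPM in all ribo-depleted libraries.

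In WT cells, naive transcripts fell and formative transcripts rose within 32 h of 2i withdrawal. In the ribo-depleted set the naive regulator Esrrb went from 594 ± 3.07 to 86.1 ± 42.4 CPM (log2 fold change -2.78 ± 0.3, adjusted p = 0.00054). The POU factor gene Pou3f1 went from 1.21 ± 0.448 to 54.7 ± 2.2 CPM (5.41 ± 0.18, adjusted p = 3.7e-07). Other naive genes fell, with log2 fold changes of -3.33 ± 0.4 for Tfcp2l1, -2.34 ± 0.39 for Nanog, -1.81 ± 0.25 for Zfp42 and -3.83 ± 0.4 for Tbx3. Formative genes rose, with 4.15 ± 0.15 for the growth factor Fgf5, 2.56 ± 0.12 for Otx2, and 2.72 ± 0.11 and 2.05 ± 0.1 for the de novo DNA methyltransferases Dnmt3b and Dnmt3a. Of 18 measured naive genes 13 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 3.4e-12, estimated-correlation p = 0.32). Of 16 formative genes 15 rose and 1 fell (1.6e-13, estimated-correlation p = 0.13). Sox2 fell by 0.81 ± 0.11 and the RNA-binding Lin28b rose by 1.35 ± 0.09. Of 11 general pluripotency genes 7 rose and 1 fell (8 and 2 adjusted over the list alone; 0.0029, estimated-correlation p = 0.27).

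Germline genes rose with the formative ones in the same ribo-depleted WT cells. Of 24 measured, 17 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 8.3e-09, estimated-correlation p = 0.055), among them Mael (2.06 ± 0.11), Taf7l (2.4 ± 0.13) and Piwil2 (1.47 ± 0.11). Targets of Wnt signalling, which the Gsk3 inhibitor in 2i turns on, were lower for 10 of 14 and higher for 2 (0.0029, estimated-correlation p = 0.17). Axin2 was at -2.36 ± 0.1 and Cdx1 at -6.33 ± 0.43. Targets of Fgf and Erk signalling, which the Mek inhibitor blocks, were higher for 9 of 16 and lower for 1 (0.0005, estimated-correlation p = 0.27). Dusp6 was at 3.72 ± 0.13, Etv4 at 3.15 ± 0.13 and Spry4 at 3.41 ± 0.17. The neural genes Sox1 (2.27 ± 0.12) and Zic1 (2.65 ± 0.44) and the endocytic receptor Lrp2 (3.96 ± 0.11) rose. The Bmp target Id3 (-2.5 ± 0.17), the cell cycle inhibitor Cdkn1a (-1.67 ± 0.11), the imprinted Plagl1 (-3.93 ± 0.23), Pglyrp1 (-6.01 ± 0.51) and Dmgdh (-4.74 ± 0.24) fell. Ehmt1 rose by 0.67 ± 0.09 and Zic2 by 0.52 ± 0.11. In all, 4921 of 18971 genes were called, 2840 higher and 2081 lower at 32 h. The share of higher calls was 57.7%, but 48.8% with DESeq2's size factors and 49.2% with DESeq2. With the line as a block the count was 7525, and with only the groups compared it was 2298. Nanog lost its call without the line WT at ESC (-2.02, adjusted p = 0.067), and Zic2 with only the groups compared (0.49, adjusted p = 0.09), and Zic2 was at 0.33 without the line Zfp281_WT. Klf4 (-1.94 ± 0.56, adjusted p = 0.055) passed with the block (-2.01, adjusted p = 0.0061), with DESeq2 (adjusted p = 0.022) and without the line Zfp281_WT (adjusted p = 1.4e-08). It was at -3.29 (adjusted p = 0.00061) without WT replicate 1 at 32 h and -1.3 (0.015) without WT replicate 2 at 32 h.

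In the ribo-depleted WT time course, camera calls were also made for glycolysis (7 of 15 higher, 3 lower, 10 and 3 adjusted over the list alone; adjusted p = 0.042, estimated-correlation p = 0.72). Nodal and Bmp targets (3 of 15 higher, 7 lower; 0.016, estimated-correlation p = 0.52) were called too, as was oxidative phosphorylation (0 of 16 higher, 5 lower; 0.0059, estimated-correlation p = 0.69). The glycolysis call ended without WT replicate 2 at ESC (0.14) or replicate 1 at 32 h (0.2), and the other 2 without WT replicate 1 at ESC (0.091 and 0.44). No call was made for imprinted genes (12 of 29 higher, 6 lower, 14 and 7 adjusted over the list alone; adjusted p = 0.075, and 0.0066 with the block, estimated-correlation p = 0.33) or histone H3 lysine 9 methylation genes (6 of 15 higher, 3 lower, 6 and 4 adjusted over the list alone; 0.81). Nor were primitive endoderm (2 of 15 higher, 2 lower; 0.8) or trophoblast genes (2 of 10 higher, 2 lower; 0.8) called. No member was called among 22 ribosomal protein, 12 2-cell-like, 11 fibroblast and 3 Magea genes.

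The polyA WT cells, which share no library with the ribo-depleted ones, gave the same directions for the genes named in both. Esrrb went from 773 ± 21.8 to 41.5 ± 1.26 CPM (log2 fold change -4.22 ± 0.15, adjusted p = 8e-09). Klf4, a naive regulator, fell by 3.32 ± 0.19 (adjusted p = 2.3e-07), and Tfcp2l1 (-4.17 ± 0.2), Nanog (-3.17 ± 0.17), Zfp42 (-2.18 ± 0.14) and Tbx3 (-5.06 ± 0.27) fell with it. Pou3f1 (6.2 ± 0.72), Otx2 (2.76 ± 0.17), Dnmt3b (2.61 ± 0.19) and Dnmt3a (1.85 ± 0.15) rose. Of 18 naive genes 15 fell and 1 rose (camera adjusted p = 1.6e-12, estimated-correlation p = 0.031, and 0.18 with the block). Of 16 formative genes 14 rose and 0 fell (7.6e-10, estimated-correlation p = 0.069, and 0.028 with the block). Sox2 (-1.1 ± 0.17), Axin2 (-2.78 ± 0.27), Cdx1 (-7.46 ± 0.7), Id3 (-2.26 ± 0.17), Cdkn1a (-1.57 ± 0.14), Plagl1 (-5.55 ± 0.31), Pglyrp1 (-8.21 ± 0.45), Dmgdh (-7.46 ± 0.63) and the Nodal inhibitor Lefty2 (-4.06 ± 0.3) fell. Lin28b (1.76 ± 0.18), Mael (2.16 ± 0.41), Piwil2 (1.59 ± 0.21), Dusp6 (2.97 ± 0.49), Etv4 (3.26 ± 0.31) and Spry4 (2.78 ± 0.4) rose. So did Sox1 (3.77 ± 0.51), Zic1 (4.32 ± 0.65), Lrp2 (4.9 ± 0.3), Ehmt1 (0.8 ± 0.16) and Zfp281 (0.54 ± 0.14, adjusted p = 0.0079). In all, 5587 of 15667 genes were called, 2802 higher and 2785 lower. The count was 3647 without WT replicate 1 at ESC, where Zfp281 lost its call (0.29, adjusted p = 0.053, and 0.065 with only the groups compared, but 0.82 without WT replicate 2), 3499 without WT replicate 1 at 32 h, where Dmgdh has no 32 h count left, and 3689 without WT replicate 2 at 32 h.

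Among the other lists of the polyA WT cells, 11 of 16 oxidative phosphorylation genes fell (14 adjusted over the list alone), Cox5a by 1.01 ± 0.16, with camera adjusted p = 6.4e-06 and estimated-correlation p = 0.27. Calls with estimated-correlation p = 0.25 were made for germline genes (16 of 24 higher, 1 lower; 8.7e-05) and Wnt targets (2 of 14 higher, 9 lower; 0.0038), and with estimated-correlation p = 0.26 for Nodal and Bmp targets (3 of 14 higher, 9 lower, 3 and 10 adjusted over the list alone; 0.0036), neural (5 of 8 higher; 0.035) and primitive streak genes (4 of 9 lower; 0.039). Also called, with estimated-correlation p = 0.27, were Fgf and Erk targets (9 of 16 higher, 1 lower; 0.002), fibroblast genes (3 of 7 higher, 4 adjusted over the list alone; 0.033) and DNA methylation genes (4 of 11 higher, 1 lower, 5 and 1 adjusted over the list alone; 0.039, and 0.05 with the block). Imprinted genes (14 of 28 higher, 3 lower, 18 and 5 adjusted over the list alone; 0.0061, estimated-correlation p = 0.39) were also called. Ribosomal protein genes had 5 of 22 lower (0 adjusted over the list alone; 0.0012, estimated-correlation p = 0.51). With the block, general pluripotency (5 of 11 higher, 1 lower) went from adjusted p = 0.07 to 0.035 (estimated-correlation p = 0.36) and the 2-cell-like list (1 of 10 higher) from 0.16 to 0.041 (estimated-correlation p = 0.45). Without WT replicate 1 at ESC the ribosomal protein (0.11), fibroblast (0.061, and 0.069 without replicate 2) and DNA methylation calls (0.085) ended, and the primitive streak call did without any of the 4 libraries (0.061 to 0.08).

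In 2i, cells labelled Zfp281 KO had lower Lefty and Lin28 transcripts than WT cells. Lefty2, an inhibitor and target of Nodal, was at 12.1 ± 1.2 CPM against 208 ± 16.1 in WT (log2 fold change -4.11 ± 0.45, adjusted p = 0.0033). Lefty1 (-2.57 ± 0.37) was lower with it. The RNA-binding protein gene Lin28a was at 77.6 ± 3.91 against 388 ± 6.7 CPM (-2.32 ± 0.1, adjusted p = 1.9e-05), and Lin28b fell by 1.57 ± 0.09 (adjusted p = 2.9e-05). Dnmt3a (-1.43 ± 0.1), the germline factor gene Dmrt1 (-2.74 ± 0.2) and the integrin gene Itgam (-3.19 ± 0.22) also fell. Higher were Gpx2 (3.6 ± 0.25), the meiotic genes Hormad1 (3.13 ± 0.26) and Smc1b (2.26 ± 0.21), and the Erk targets Etv4 (2.49 ± 0.13) and Spry4 (2.67 ± 0.17). Id3 (1.51 ± 0.13), Eomes (0.99 ± 0.1), Cdx2 (2.15 ± 0.35), Cox7b2 (3.41 ± 0.33) and the naive genes Nr0b1 (0.76 ± 0.13), Klf5 (0.64 ± 0.13) and Tet2 (0.62 ± 0.14) were also higher. Of 16 Fgf and Erk targets 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0016, estimated-correlation p = 0.65). Of 24 germline genes 8 rose and 3 fell (9 and 5 adjusted over the list alone; 0.032, and 0.17 without WT replicate 1, estimated-correlation p = 0.65). Among 18 naive genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; 0.0016, estimated-correlation p = 0.73). The formative list had 3 of 16 higher and 5 lower (5 and 7 adjusted over the list alone; 0.32).

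X-linked genes were higher in these Zfp281 KO cells in 2i, 20 of 40 listed genes against 0 lower (29 and 0 adjusted over the list alone; camera adjusted p = 1.7e-09, estimated-correlation p = 0.73). Examples were Hdac6 (log2 fold change 1.05 ± 0.18), Eda2r (1.04 ± 0.18) and Efhc2 (4.42 ± 0.83, adjusted p = 0.028). The median over X-linked genes of Zfp281_WT minus WT, both wild type, was -0.25 on the log2 scale at ESC. The p53 list had 6 of 13 higher and 0 lower (9 and 0 adjusted over the list alone; 0.0016) and the 2-cell-like list 3 of 12 higher (4 adjusted over the list alone; 0.0016), including Sp110 (1.76 ± 0.32), both with estimated-correlation p = 0.73. The fibroblast list had 1 of 11 genes lower and a median of -1.59 (adjusted p = 0.32) in this comparison, where Zfp281_WT has counts in 89.2% of olfactory receptor genes. In all, 2618 genes were called, 1613 higher and 1005 lower. The count was 6537 without the line WT, 655 without KO clone 1, 539 without KO clone 2 and 5511 without the line Zfp281_WT. Calls were lost without KO clone 1 or 2 for Lefty1, Nr0b1, Klf5, Eda2r, Tet2 and Efhc2, of which Nr0b1, Eda2r and Efhc2 are X-linked. Tet2 (log2 value 0.39) and Efhc2 also lost theirs without WT replicate 2, and Efhc2 with no filter (adjusted p = 0.095). Efhc2 was at 7.49 without WT replicate 1. Without KO clone 2 alone they were lost for Lefty2, Cdx2, Hdac6 and Sp110 (also with only the groups compared, 0.065).

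At 16 h, cells labelled Zfp281 KO had higher naive and lower formative transcripts than WT cells. Lin28a was at 97.4 ± 2.48 against 842 ± 32.7 CPM (log2 fold change -3.11 ± 0.09, adjusted p = 8.5e-07), and Dnmt3a at 115 ± 8.82 against 568 ± 51.6 CPM (-2.3 ± 0.1, adjusted p = 1e-05). Lin28b (-2.23 ± 0.17), Dnmt3b (-1.42 ± 0.09), Sall2 (-1.43 ± 0.1), Otx2 (-0.87 ± 0.12) and Lefty2 (-2.59 ± 0.22) were lower. Nr5a2 (0.85 ± 0.08), Tfcp2l1 (1.16 ± 0.12), Nanog (0.92 ± 0.14), Esrrb (0.71 ± 0.1) and Prdm14 (1.35 ± 0.17) were higher. Of 18 naive genes 12 rose and 0 fell (camera adjusted p = 1.7e-07, estimated-correlation p = 0.64). Of 16 formative genes 11 fell and 2 rose (13 and 2 adjusted over the list alone; 2e-05, estimated-correlation p = 0.64). The largest falls under the naming rule included Foxr2 (-5.71 ± 0.28), Vrtn (-4.02 ± 0.13), the carbonic anhydrase gene Car4 (-3.69 ± 0.22) and Spred3 (-3.28 ± 0.16). Gpx2 (3.53 ± 0.23), Hormad1 (2.38 ± 0.1), Kdr (2.34 ± 0.36) and Sp110 (4.02 ± 0.48) rose. The imprinted noncoding RNA genes Meg3 (-1.18 ± 0.11) and Rian (-1.14 ± 0.08) and the glycolytic Ldha (-1.02 ± 0.1) fell. Zic2 fell by 0.52 ± 0.1 (adjusted p = 0.0061), Ehmt1 fell by 0.35 ± 0.08 (adjusted p = 0.012) and Ehmt2 rose by 0.3 ± 0.08 (adjusted p = 0.024).

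List tests at 16 h, each with estimated-correlation p = 0.64, were called for general pluripotency (2 of 11 higher, 6 lower, 2 and 8 adjusted over the list alone; 0.011) and glycolysis (2 of 15 higher, 5 lower; 0.048). The same estimated p applied to the calls of primitive streak genes (4 of 7 higher, 5 adjusted over the list alone; 0.048, and 0.057 or 0.081 without WT replicate 1 or 2) and 2-cell-like genes (4 of 11 higher; 1.8e-05). X-linked genes were higher for 16 of 40 and lower for 3 (18 and 3 adjusted over the list alone; 0.0037, estimated-correlation p = 0.83). In the Zfp281 KO cells at 16 h, 4329 of 15139 genes were called, 2314 higher and 2015 lower. The count was 7008 without WT replicate 1, 2137 without KO clone 1 and 2138 without KO clone 2, where Ehmt1 (adjusted p = 0.078 without clone 1 and 0.14 without clone 2) and Ehmt2 (0.25 and 0.097) lost their calls. Fitted jointly with the ESC and 32 h libraries, Tfcp2l1 (adjusted p = 0.056), Nanog (0.15), Esrrb (0.086) and Ehmt2 (0.1) were not called.

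At 32 h, naive genes were higher and the de novo DNA methyltransferases lower in cells labelled Zfp281 KO. The X-linked Nr0b1 was at 113 ± 10.1 against 24.4 ± 5.59 CPM in WT (log2 fold change 2.21 ± 0.14, adjusted p = 1.5e-05). Nr5a2 (2.02 ± 0.15), Prdm14 (2.24 ± 0.27), Tet2 (1.66 ± 0.15), Zfp42 (1.38 ± 0.25), Klf2 (1.32 ± 0.24) and Gbx2 (1.33 ± 0.2) were higher as well. Of 18 naive genes 14 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 2.9e-10, estimated-correlation p = 0.85). Dnmt3a was at 183 ± 9.8 against 535 ± 18.3 CPM (-1.55 ± 0.1). Dnmt3b (-1.31 ± 0.11), Car14 (-1.88 ± 0.16), Pim2 (-1.53 ± 0.15) and Sall2 (-1 ± 0.1) fell too. The formative list had 11 of 16 lower and 4 higher (0.0011, estimated-correlation p = 0.85). Grhl2 (0.62 ± 0.07) and Fgf15 (0.75 ± 0.1) were among the higher. Lin28a was at 126 ± 14.7 against 840 ± 14.2 CPM (-2.74 ± 0.1, adjusted p = 1.9e-06), Lin28b fell by 2.11 ± 0.09 and Sox2 rose by 0.94 ± 0.11.

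Gpx2 rose from 2.38 ± 0.381 CPM in WT to 48.4 ± 9.13 CPM (log2 fold change 4.35 ± 0.21) in these Zfp281 KO cells at 32 h. Gpr83 (3.55 ± 0.28) and Hormad1 (3.16 ± 0.25) were also higher. Foxr2 (-4.03 ± 0.19), Car4 (-4.08 ± 0.15) and Itgam (-3.97 ± 0.23) were lower. Id3 (1.98 ± 0.17) and Eomes (1.51 ± 0.11) rose. The activin antagonist gene Fst (-2.12 ± 0.14), Sox1 (-1.17 ± 0.11), Zic1 (-3.03 ± 0.45), the meiotic Sycp3 (-1.56 ± 0.1), Tagln (-1.73 ± 0.26) and the imprinted growth factor gene Igf2 (-2.4 ± 0.25) fell. Zic2 was at 91.7 ± 7.08 against 151 ± 20.8 CPM (-0.72 ± 0.11, adjusted p = 0.00098) and Ehmt2 was higher (0.71 ± 0.11, adjusted p = 0.0013). The 2-cell-like list had 6 of 12 higher and 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 2.9e-05), with Sp110 at 2.31 ± 0.3 and Zfp352 at 2.95 ± 0.5. X-linked genes (15 of 40 higher, 5 lower, 19 and 5 adjusted over the list alone; 0.012) were called. Calls were also made for p53 targets (7 of 13 higher, 1 lower, 8 and 1 adjusted over the list alone; 0.012) and oxidative phosphorylation (3 of 16 higher, 2 adjusted over the list alone; 0.0042). Each of these 4 lists had estimated-correlation p = 0.85, and without WT replicate 2 the X-linked (0.32) and p53 calls (0.11) ended. Xist, the RNA that silences an X chromosome in differentiated female cells, was at 112 and 116 CPM in the KO clones and 41.9 and 12.9 CPM in WT (2.05 ± 0.53, adjusted p = 0.037, and 3.15 without WT replicate 1). The fibroblast list had a median of -2.51, or -1.77 with a gene at 0 placed at its limit, and 1 of 11 lower (adjusted p = 0.23), where Zfp281_WT has counts in 87.0% of olfactory receptor genes. In all, 5400 genes were called, 3145 higher and 2255 lower. The count was 2498 without KO clone 1, where Klf2 (adjusted p = 0.051) and Xist (0.17) lost their calls, and 2598 without KO clone 2, where Xist did (0.17). With only the groups compared, Zfp42 (0.059), Klf2 (0.058) and Xist (0.14) lost theirs, as Xist did with no filter (0.1).

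The response to 2i withdrawal itself differed between Zfp281 KO and WT cells for 787 genes, 369 with a higher and 418 with a lower 32 h to ESC ratio in the KO (46.9% higher, but 55% with DESeq2). Naive genes had higher ratios, with interaction log2 values of 1.64 ± 0.2 for Nr5a2 (adjusted p = 0.0043), 1.45 ± 0.19 for Nr0b1 (0.0052), 1.71 ± 0.35 for Prdm14 (0.033) and 1.64 ± 0.34 for Klf2 (0.039). Ratios were lower for the X-linked Pim2 (-1.97 ± 0.23, adjusted p = 0.0035), Fgf5 (-1.07 ± 0.22, 0.027) and Etv4 (-1.97 ± 0.17, 0.0016). Fst (-2.22 ± 0.19, 0.0016) and the kinesin gene Kif1a (-4.02 ± 0.16, 1.5e-05) had lower and Ap3b2 (2.44 ± 0.18, 0.0011) a higher ratio. In 2i, Etv4 (2.49) and 6 of 16 Fgf and Erk targets were already higher in the KO, so their ratios reflect the 2i level too. The naive list had 5 of 18 higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 3.3e-13), and the formative list 0 higher and 5 of 16 lower (0 and 7 adjusted over the list alone; 0.00097). Fgf and Erk targets (5 of 16 lower, 1 higher and 6 lower adjusted over the list alone; 0.019), germline genes (2 of 24 lower; 0.025) and Nodal and Bmp targets (1 of 15 higher, 1 lower, 8 and 2 adjusted over the list alone; 0.014) were called with them. These 5 lists had estimated-correlation p = 0.51. Oxidative phosphorylation (0 of 16 called; 0.014, estimated-correlation p = 0.73) and X-linked genes (3 of 40 lower; 0.0095, estimated-correlation p = 0.97) were called too. Without WT replicate 1 at ESC the calls of Nodal and Bmp targets (0.074), Fgf and Erk targets (0.085, and 0.068 without replicate 2) and oxidative phosphorylation (0.64, with the direction turned) ended. The last also ended without WT replicate 2 at 32 h (0.096) or KO clone 1 (0.066) or 2 (0.11) at ESC. Germline (0.074 and 0.056) and X-linked calls (0.77, and 0.82 with the direction turned) ended without WT replicate 2 at ESC or replicate 1 at 32 h. With the line as a block the count was 2605, DNA methylation (adjusted p = 0.04 in place of 0.06) and imprinted genes (0.027 in place of 0.092) were called, both with estimated-correlation p = 0.36, and Klf2 was not (1.68, adjusted p = 0.17). The count was 1771 and 1675 without WT replicate 1 or 2 at ESC, 97 and 62 without KO clone 1 or 2 at ESC, 109 and 143 without KO clone 1 or 2 at 32 h, and 2988 without the line Zfp281_WT. Calls were lost for Nr5a2 without KO clone 2 at ESC and for Nr0b1 without clone 1 or 2 at ESC. Prdm14 lost its call without any of the 4 KO libraries or with no filter (0.12). Klf2 did without any of 6 of the 8 libraries. Fgf5 did without WT replicate 1 at 32 h or any of the 4 KO libraries.

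In 2i, genes of the Magea and 2-cell-like lists were higher in Ehmt1 KO than in WT cells. Magea4, of a cancer/testis gene family on the X chromosome, was at 47.6 ± 2.76 CPM in Ehmt1 KO with 1936 counts, against 0 counts in WT, at least 649-fold higher. Magea8 was at least 233-fold and Wfdc15a at least 121-fold higher, and all 7 measured genes of the Magea and Wfdc15a list rose (camera adjusted p = 1.3e-10, estimated-correlation p = 0.0023). Asz1, a gene of the piRNA pathway, had 399 counts against 1 in WT (ratio 401, 95% interval 71.6 to 15900). Minar2 (at least 148-fold) and Cd3d (at least 118-fold) were higher as well. All 10 measured 2-cell-like genes rose (8.2e-05, estimated-correlation p = 0.7), among them Usp17la (log2 fold change 4.26 ± 0.51), Zfp352 (4.49 ± 0.72) and Zscan4d (2.24 ± 0.48). Of 24 germline genes 11 rose and 2 fell (11 and 3 adjusted over the list alone; 0.087), with Smc1b at 4.55 ± 0.57, Sohlh2 at 1.41 ± 0.2, Dazl at 1.2 ± 0.25 and Sycp3 at -1.63 ± 0.28.

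In the same Ehmt1 KO cells in 2i, 7 of 18 naive genes rose and 1 fell (camera adjusted p = 0.21). Klf4 was at 1.25 ± 0.16, Jam2 at 1.68 ± 0.25, Fbxo15 at 0.7 ± 0.13 and Nr0b1 at -0.84 ± 0.25 (adjusted p = 0.023). Lin28a fell by 1.12 ± 0.13. Phyhd1 (-4.08 ± 0.32), Gata4 (-2.6 ± 0.46) and Sox1 (-2.11 ± 0.64, adjusted p = 0.028) fell. The imprinted Slc38a4 (2.27 ± 0.19) and Igf2r (1.28 ± 0.13), the DNA demethylase Tet3 (1.97 ± 0.23), the p53 target Ccng1 (1.13 ± 0.16), the X-linked Klhl13 (2.34 ± 0.19) and Xist (1.87 ± 0.47, adjusted p = 0.01) rose. Camera called p53 targets (7 of 13 higher, 1 lower; 0.043, and 0.15 without KO clone 2, estimated-correlation p = 0.7). It also called ribosomal protein genes (3 of 22 lower, 2 adjusted over the list alone; 0.015, estimated-correlation p = 0.86), but not without WT replicate 1 (0.85) or KO clone 1 (0.063). In all, 4214 genes were called, 2312 higher and 1902 lower, and 2590 without WT replicate 1 and 2623 without KO clone 1. Nr0b1 and Sox1 lost their calls without any of the 4 libraries, and Xist without WT replicate 1 or KO clone 1. Sox1 also did with no filter (adjusted p = 0.085).

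At 32 h, Ehmt1 KO cells had higher naive genes than WT cells. Klf4 was at 17.9 ± 1.72 against 2.7 ± 0.466 CPM (log2 fold change 2.73 ± 0.19, adjusted p = 1.3e-06) and Esrrb at 117 ± 6.99 against 41.5 ± 1.26 CPM (1.49 ± 0.14). Tbx3 (2.56 ± 0.26), Prdm14 (2.59 ± 0.26), Tcl1 (2.33 ± 0.22) and Zfp42 (1.55 ± 0.14) were higher. Of 18 naive genes 13 rose and 0 fell (camera adjusted p = 1.3e-07, estimated-correlation p = 0.081). The formative list had 1 of 16 higher and 1 lower (0 and 1 adjusted over the list alone; 0.54), which were Otx2 (0.48 ± 0.15, adjusted p = 0.034) and Cdh2 (-0.94 ± 0.17). Neural genes Sox1 (-3.76 ± 0.51) and Zic1 (-4.07 ± 0.62) and the homeobox gene Hoxb1 (-3.87 ± 0.48) fell, in a neural list with 2 of 8 higher and 3 lower (2 and 4 adjusted over the list alone; 0.28). The Magea list was higher for all 7 measured genes (1.2e-10, estimated-correlation p = 0.0022), Magea8 at least 336-fold and Magea5 at least 138-fold, and Ptprq was at least 109-fold higher. Asz1 (6.06 ± 0.57), Usp17la (3.16 ± 0.46), Zfp352 (2.71 ± 0.59), Plagl1 (2.29 ± 0.3), Id3 (1.2 ± 0.17), Lama1 (2.15 ± 0.36) and Xist (2.02 ± 0.4) rose. Lin28b (-1.2 ± 0.18), Fst (-1.88 ± 0.3) and Sycp3 (-1.76 ± 0.27) fell. Of 10 2-cell-like genes 8 rose (0.002, estimated-correlation p = 0.9). In all, 4163 genes were called, 2372 higher and 1791 lower. The count was 2203 without WT replicate 1, 2191 without WT replicate 2, where Asz1 has no WT count left, and 2484 without KO clone 1, and Otx2 lost its call without WT replicate 2 (adjusted p = 0.28) or KO clone 1 (0.2) and with only the groups compared (0.06).

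The response to 2i withdrawal differed between Ehmt1 KO and WT cells for 291 genes, 189 with a higher and 102 with a lower 32 h to ESC ratio in the KO. The naive list had 9 of 18 higher and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 1.3e-13, estimated-correlation p = 0.027, and 0.24 with the line as a block). Interaction log2 values were 1.66 ± 0.19 for Esrrb (adjusted p = 0.0022), 1.41 ± 0.19 for Zfp42 (0.0043), 2.29 ± 0.34 for Prdm14, 1.41 ± 0.22 for Nanog (0.0093), 1.17 ± 0.24 for Id3 (0.027) and 3.65 ± 0.63 for Spic (0.014). They were negative for the neurofilament gene Nefm (-4.12 ± 0.48), Lrp2 (-2.51 ± 0.37), Cdx2 (-3.83 ± 0.87, 0.046) and Gabra3 (-6.02 ± 0.91), whose value rests on 3 counts in WT at ESC. Nodal and Bmp targets (1 of 14 higher, 1 lower, 8 and 1 adjusted over the list alone; 0.0027, estimated-correlation p = 0.41) were higher by camera. So was oxidative phosphorylation (0 of 16 called; 0.0052, estimated-correlation p = 0.65). Germline genes (0 of 24 called, 1 lower adjusted over the list alone; 0.0052, estimated-correlation p = 0.41) and 2-cell-like genes (0 of 10 called; 0.029, estimated-correlation p = 0.65) were lower. Most 2-cell-like genes were higher in the KO at both stages. Without WT replicate 1 at ESC, the oxidative phosphorylation and germline calls ended. The germline call also ended without KO clone 1 at ESC or WT replicate 2 at 32 h. The 2-cell-like call ended without any of the 8 libraries but KO clone 1 at ESC. With the line as a block the count was 1361, and Fgf and Erk targets (adjusted p = 0.024 in place of 0.067) and neural genes (0.03 in place of 0.067) were called, both with estimated-correlation p = 0.27. DESeq2 gave 616 genes and a fit of only the groups compared 132. The count was 103 without WT replicate 1 at ESC, 55 and 42 without WT replicate 1 or 2 at 32 h, and 149 and 127 without KO clone 1 at ESC or 32 h. Without WT replicate 1 at 32 h calls were lost for Nanog and Spic, and without replicate 2 for Prdm14 and Spic. Without WT replicate 1 at ESC they were lost for Spic and Gabra3. Id3 and Cdx2 lost theirs without any of 6 of the 8 libraries. Nanog (0.054), Id3 (0.064) and Cdx2 (0.11) did with only the groups compared, and Cdx2 with no filter (0.11).

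Few genes passed the test between cells labelled Zic2 KO and WT cells. In 2i, 43 genes were called, 25 higher and 18 lower. Among them the formative factor gene Otx2 fell by 1.43 ± 0.18 on the log2 scale (adjusted p = 0.014). Dnmt3l, a cofactor of the de novo DNA methyltransferases, was at 83.7 ± 8.63 against 266 ± 9.95 CPM (-1.67 ± 0.24, adjusted p = 0.016). Germline genes Dazl (1.67 ± 0.25), Sohlh2 (1.52 ± 0.2) and Fkbp6 (1.69 ± 0.29) were higher. So were Crxos (2.39 ± 0.39), Il34 (1.87 ± 0.28) and Slc38a4 (1.03 ± 0.18, adjusted p = 0.04). Pkd1l2 (-3.26 ± 0.49) and Rsph4a (-2.43 ± 0.39) were lower. Of 24 germline genes 3 rose (6 adjusted over the list alone; camera adjusted p = 1.7e-06, estimated-correlation p = 0.27). In all, 0 of 10 2-cell-like genes were called over all genes against 10 higher adjusted over the list alone (3.3e-10, estimated-correlation p = 0.27). Camera gave lower values for glycolysis (0 of 15 called, 1 higher and 7 lower adjusted over the list alone; 7.9e-07, estimated-correlation p = 0.27) and oxidative phosphorylation (0 of 16 called; 0.035, estimated-correlation p = 0.61). The same direction was given for general pluripotency (0 of 11 called, 2 lower adjusted over the list alone; 0.006), imprinted genes (1 of 28 higher, 1 higher and 2 lower adjusted over the list alone; 0.041) and ribosomal protein genes (0 of 22 called; 0.00016), each of these 3 with estimated-correlation p = 0.57. Without WT replicate 1 oxidative phosphorylation (median log2 value 0.04 in place of -0.08, camera adjusted p = 0.39) and ribosomal protein genes (0.01 in place of -0.15, 0.71) lost their calls and turned, and general pluripotency had -0.11 in place of -0.23 (0.035). Without WT replicate 2 the medians of the first 2 lists were -0.19 and -0.28. Calls also ended without KO clone 1 for oxidative phosphorylation (0.088) and imprinted genes (0.19, and 0.6 without WT replicate 2). The count was 0 by edgeR without WT replicate 1, KO clone 1 or KO clone 2, where the 10 genes named lost their calls (adjusted p = 0.08 to 0.41), and 214 without WT replicate 2, where Crxos did (0.064, and 0.066 with no filter). Slc38a4 lost its call with only the groups compared (0.066). The count was 276 with DESeq2, 207 with only the groups compared and 94 with no filter, and 1545 genes had an unadjusted p under 0.05.

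At 32 h, 12 genes were called in Zic2 KO against WT, 7 higher and 5 lower. Id3 was at 15.9 ± 0.468 against 5.12 ± 0.0814 CPM (log2 fold change 1.64 ± 0.17, adjusted p = 0.0019). Sohlh2 (1.56 ± 0.2), the naive gene Fbxo15 (0.93 ± 0.13) and Arhgef26 (1.25 ± 0.11, adjusted p = 0.00052) were higher, and Rab25 (-2.58 ± 0.27) and Tmcc3 (-2.09 ± 0.28) lower. The naive list had 1 of 18 higher (4 adjusted over the list alone; camera adjusted p = 0.00014) and the 2-cell-like list 0 of 10 called (9 higher adjusted over the list alone; 1.8e-08), both with estimated-correlation p = 0.59. The count was 2 without any of the 4 libraries, and Arhgef26 was called in each of these fits. Id3 lost its call without WT replicate 1 or 2, Rab25 without KO clone 1 or 2, and Sohlh2, Fbxo15 and Tmcc3 without any library. DESeq2 gave 165 genes, 79 higher and 86 lower, no filter 48 and a fit of only the groups compared 1516. That fit lacks Ehmt1 KO and double KO, whose chi-square per gene was 29.84 and 25.11 (Zic2 KO 6.39, WT 7.15). For the difference in response, edgeR called 0 genes with 725 at an unadjusted p under 0.05, DESeq2 called 23, the block 50, and edgeR without WT replicate 2 at ESC 8. Camera gave higher ratios in Zic2 KO for glycolysis (1 higher adjusted over the list alone; 0.0014), naive genes (2 higher adjusted over the list alone; 0.0098), oxidative phosphorylation (0.0038) and ribosomal protein genes (0.0014). It gave lower ones for germline genes (1 lower adjusted over the list alone; 0.00047). These lists had estimated-correlation p = 0.72 or 0.73. Without WT replicate 1 at ESC the calls of glycolysis (0.081), oxidative phosphorylation (0.74) and ribosomal protein genes (0.78) ended, with medians of 0.14, 0.02 and -0.02 in place of 0.25, 0.13 and 0.16. The glycolysis call also ended without KO clone 1 at ESC (0.1), and the naive one without WT replicate 2 (0.059) or KO clone 1 (0.099) at ESC or WT replicate 1 (0.081) or KO clone 2 (0.094) at 32 h. With the block a call was also made for imprinted (0.012 in place of 0.28) and 2-cell-like genes (0.0081 in place of 0.12), both with estimated-correlation p = 0.45.

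In 2i, cells labelled double KO had higher Magea and 2-cell-like genes than WT cells. Magea8 was at least 236-fold and Wfdc15a at least 127-fold higher than in WT, and all 7 genes of the Magea list rose (camera adjusted p = 2.1e-08, estimated-correlation p = 0.0051). Asz1 had a ratio of 437 (95% interval 78 to 17300). All 10 2-cell-like genes rose (8.6e-05, estimated-correlation p = 0.49), with Usp17la at 4.94 ± 0.51 and Zfp352 at 4.87 ± 0.72 on the log2 scale. Of 24 germline genes 12 rose and 3 fell (13 and 4 adjusted over the list alone; 0.03, estimated-correlation p = 0.49), with Dazl at 2.42 ± 0.25 and Smc1b at 5.48 ± 0.57. Dppa3, a maternal and naive factor gene, was at 153 ± 110 against 1.99 ± 1.62 CPM (6.24 ± 1.22), and Jam2 rose by 2.05 ± 0.26. Of 22 ribosomal protein genes 16 fell and 0 rose (6.2e-06, estimated-correlation p = 0.49; median -0.44, and -0.24 without WT replicate 1), with Rps4x at -0.64 ± 0.1, Rpl4 at -0.43 ± 0.08 and Rpl8 at -0.55 ± 0.12. Oxidative phosphorylation had 5 of 16 lower (0.0052, estimated-correlation p = 0.56), Cox4i1 at -0.55 ± 0.12. Nodal and Bmp targets had 6 of 14 lower (7 adjusted over the list alone; 0.019, estimated-correlation p = 0.49), with Msx2 at -1.67 ± 0.24 and Bmp4 at -2.13 ± 0.42. Gap43 (-4.15 ± 0.78), Lin28a (-1.66 ± 0.13), Pou5f1 (-0.56 ± 0.11), Sox1 (-3.88 ± 0.8) and Otx2 (-0.85 ± 0.17) fell, and Slc38a4 (2.39 ± 0.19) rose. Without WT replicate 1 the germline, Nodal and Bmp target and oxidative phosphorylation calls ended, Rpl8 was at -0.34 and Cox4i1 at -0.31. The first also did without KO clone 2, the second without KO clone 1. All ESC ribosomal protein calls share WT replicate 1 (Rpl4 at 4290 CPM, replicate 2 at 3650). In all, 6166 genes were called, 3272 higher and 2894 lower, 3855 without WT replicate 1 and 3386 with only the groups compared, where Rpl4 (adjusted p = 0.098), Rpl8 (0.06), Cox4i1 (0.071) and Pou5f1 (0.057) lost their calls.

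At 32 h, naive genes were higher and formative genes lower in the cells labelled double KO than in WT cells. Esrrb was at 230 ± 22.4 against 41.5 ± 1.26 CPM (log2 fold change 2.47 ± 0.14, adjusted p = 1.8e-07) and Nanog at 353 ± 8.27 against 72.3 ± 6.4 CPM (2.29 ± 0.17). Fbxo15 (2.31 ± 0.14), Klf4 (3.17 ± 0.19), Prdm14 (3.54 ± 0.26) and Jam2 (3.99 ± 0.3) were higher. Of 18 naive genes 15 rose and 1 fell (camera adjusted p = 3e-09, estimated-correlation p = 0.043). Of 16 formative genes 7 fell and 0 rose (0.0015, estimated-correlation p = 0.41). Sall2 was at -0.92 ± 0.19, Pim2 at -1.6 ± 0.34, Dnmt3b at -0.78 ± 0.18 and Dnmt3a at -0.41 ± 0.14 (adjusted p = 0.037). Sox1, a neural factor gene, was at 0.803 ± 0.104 against 43.6 ± 12.3 CPM (-5.75 ± 0.58), and Zic1 (-5.72 ± 0.72), Hoxb1 (-5.17 ± 0.53) and Tbx15 (-5 ± 0.61) fell with it. The neural list had 5 of 8 lower and 2 higher (6 and 2 adjusted over the list alone; 0.15). Id3 (2.49 ± 0.17), Lefty2 (2.29 ± 0.29), Asz1 (5.93 ± 0.57), Tfap2c (1.75 ± 0.27) and Usp17la (4.18 ± 0.47) rose. Fst (-2.28 ± 0.3), Lin28b (-1.67 ± 0.18), Zfp281 (-0.72 ± 0.14, adjusted p = 0.0013) and the heterochromatin protein gene Cbx3 (-0.74 ± 0.13) fell. All 7 Magea list genes (2.3e-08, estimated-correlation p = 0.0059) and 9 of 10 2-cell-like genes (0.00044, estimated-correlation p = 0.65) rose. X-linked genes (2 of 40 higher, 16 lower, 4 and 19 adjusted over the list alone; 0.032, estimated-correlation p = 0.41) were called, but not without WT replicate 1 (0.1) or KO clone 2 (0.11), where Zic1 has no KO count left. Ribosomal protein genes had 6 of 22 lower (4 adjusted over the list alone; 0.012, and 0.065 without WT replicate 2, estimated-correlation p = 0.8). In all, 6129 genes were called, 3345 higher and 2784 lower. The count was 3745 without WT replicate 1, where Pim2 (-0.97, adjusted p = 0.051) and Dnmt3a (0.12) lost their calls, and 3848 without WT replicate 2, where Dnmt3a did (0.12) and Asz1 has no WT count left. Dnmt3a also did without KO clone 1 (-0.25).

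**Figure D2:**
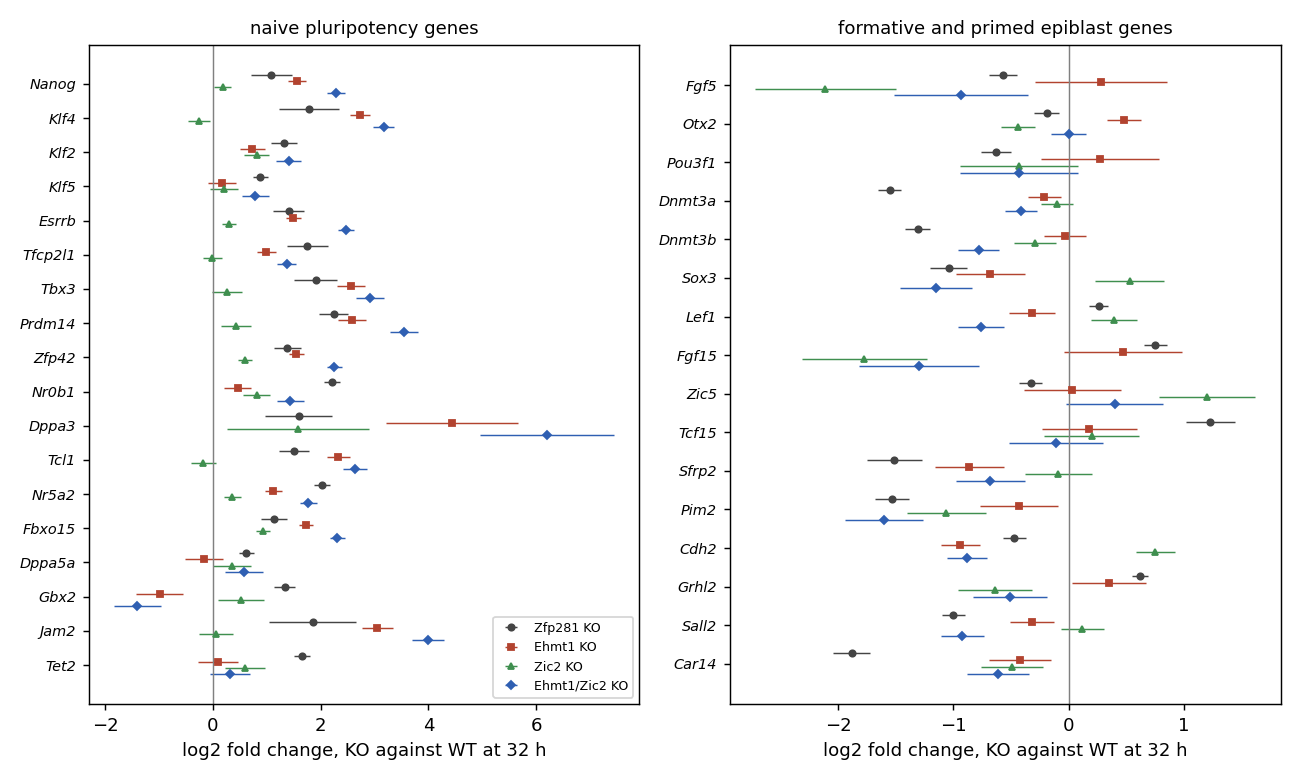
Log2 fold change of KO against WT at 32 h (x axis, with bars of 1 standard error) for naive genes (left) and formative and primed genes (right), with 1 marker per KO genotype. Esrrb stands at 1.49 in Ehmt1 KO and 2.47 in the double KO, and Dnmt3a at -1.55 in Zfp281 KO and -0.41 in the double KO.

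The response to 2i withdrawal differed between double KO and WT cells for 829 genes, 483 with a higher and 346 with a lower 32 h to ESC ratio in the double KO. Interaction log2 values were 2.76 ± 0.19 for Esrrb (adjusted p = 3.1e-05), 2.67 ± 0.25 for Klf4, 2.03 ± 0.22 for Nanog, 2.58 ± 0.33 for Prdm14, 2.81 ± 0.39 for Lefty2 and 3.08 ± 0.24 for Id3. They were -3.19 ± 0.5 for Pim2, -1.47 ± 0.25 for Dnmt3b, -3.73 ± 0.37 for Lrp2 and -7.31 ± 0.89 for Gabra3, with 3 counts in WT at ESC. The naive list had 13 of 18 higher and 0 lower (14 and 1 adjusted over the list alone; camera adjusted p = 1.4e-15, estimated-correlation p = 0.015, and 0.18 with the line as a block). Nodal and Bmp targets had 6 of 14 higher and 1 lower (10 and 1 adjusted over the list alone; 4.8e-05, estimated-correlation p = 0.22). Lower ratios were given for formative (5 of 16, 1 higher and 6 lower adjusted over the list alone; 0.014, estimated-correlation p = 0.39), germline (1 of 24, 2 adjusted over the list alone; 0.0014, estimated-correlation p = 0.35) and neural genes (2 of 8, 3 adjusted over the list alone; 0.028, estimated-correlation p = 0.26). Oxidative phosphorylation (0 of 16 called, 6 higher adjusted over the list alone; 6.8e-05, estimated-correlation p = 0.39), primitive streak (1 of 9 higher; 0.027, estimated-correlation p = 0.22) and ribosomal protein genes (0 of 22 called; 0.017, estimated-correlation p = 0.77) were higher by camera. The primitive streak call ended without WT replicate 1 or 2 or KO clone 1 at ESC, or WT replicate 1 or KO clone 2 at 32 h (0.052 to 0.11). The ribosomal protein call ended without WT replicate 1 (0.91) or KO clone 2 (0.096) at ESC or WT replicate 1 at 32 h (0.059). The neural call ended without WT replicate 1 or 2 or KO clone 2 at ESC, or KO clone 1 at 32 h (0.075 to 0.15), and the formative one without KO clone 2 at ESC (0.084). With the line as a block the count was 2611 and 2-cell-like genes were called (adjusted p = 0.011 in place of 0.11, estimated-correlation p = 0.51). DESeq2 gave 1334 genes and a fit of only the groups compared 374. The count was 348 and 1334 without WT replicate 1 or 2 at ESC, 280 and 304 without WT replicate 1 or 2 at 32 h, and 527 without KO clone 1 at 32 h.

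Set against the single KO cells at 32 h, the double KO cells differed from Ehmt1 KO for 35 genes and from Zic2 KO for 5632. Against Ehmt1 KO, 18 genes were higher and 17 lower (51.4% higher, but 44.4% with DESeq2). Esrrb was at 0.98 ± 0.13 (adjusted p = 0.017), Id3 at 1.29 ± 0.16, Lefty2 at 1.53 ± 0.28 (adjusted p = 0.045), Rimkla at 1.79 ± 0.28, and Aard at 1.47 ± 0.2. The chemokine gene Cxcl12 was at -1.9 ± 0.19 (adjusted p = 0.0028) and Efhd1 at -2.2 ± 0.31. The naive list had 1 of 18 higher (11 adjusted over the list alone; camera adjusted p = 3.4e-11, estimated-correlation p = 0.048). The formative list had 0 of 16 called (5 lower adjusted over the list alone; 5.5e-06, estimated-correlation p = 0.24), and the 2-cell-like list 0 of 10 (0.011, and 0.6 without double KO clone 2, estimated-correlation p = 0.6). The count of 35 was 280 without Ehmt1 KO clone 1, 1 without Ehmt1 KO clone 2, 0 by edgeR without double KO clone 1 and 21 without double KO clone 2. It was 261 with DESeq2, 69 with no filter and 0 with only the groups compared, while 2036 genes had an unadjusted p under 0.05. All 7 genes named lost their calls without double KO clone 1 (adjusted p = 0.11 to 0.2) and in the fit of only the groups compared (0.52 to 0.64). All but Cxcl12 did without Ehmt1 KO clone 2. Esrrb, Lefty2, Aard and Efhd1 did without double KO clone 2, and Lefty2 with no filter (0.1).

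Against Zic2 KO, the double KO cells at 32 h had 3135 genes higher and 2497 lower. Esrrb (2.18 ± 0.14), Klf4 (3.42 ± 0.19), Nanog (2.1 ± 0.16), the growth factor gene Nodal (2.24 ± 0.28), Asz1 (5.71 ± 0.56) and Otx2 (0.45 ± 0.15, adjusted p = 0.037) were higher. Ddx60 was at 46.7 ± 1.66 against 0.104 ± 0.0273 CPM (8.74 ± 0.4). Sox1 (-6.34 ± 0.59), Sp8 (-4.49 ± 0.69) and the cyclin gene Ccnd2 (-4.26 ± 0.74) were lower. Naive genes had 12 of 18 higher and 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 8.4e-08, estimated-correlation p = 0.083). All 7 Magea list genes were higher (8.9e-09, estimated-correlation p = 0.0044). Formative genes (1 of 16 higher, 4 lower, 1 and 5 adjusted over the list alone; 0.047, estimated-correlation p = 0.68) were lower by camera, but not called without Zic2 KO clone 2 (0.08) or double KO clone 1 (0.2). Ribosomal protein genes had 3 of 22 lower (1 adjusted over the list alone; 0.0068, estimated-correlation p = 0.72). The count was 3358 without Zic2 KO clone 1 and 3131 without Zic2 KO clone 2, and Otx2 lost its call without Zic2 KO clone 1 (adjusted p = 0.16), Zic2 KO clone 2 (0.12) or double KO clone 2 (0.19). For the departure of the double KO effect from the sum of the single effects, edgeR called 0 of 15667 genes, with 891 at an unadjusted p under 0.05, 13 by DESeq2 and 1 by edgeR without Ehmt1 KO clone 1. Camera placed naive, Nodal and Bmp target and trophoblast genes above the sum and neural (2 adjusted over the list alone), formative, 2-cell-like, DNA methylation (1 adjusted over the list alone) and H3 lysine 9 methylation genes under it (0.0021 to 0.044), each with estimated-correlation p = 0.48. Each of these 8 calls ended without at least 1 of 7 libraries, all but WT replicate 1 (0.056 to 0.39), and all but the 2-cell-like call ended without Ehmt1 KO clone 2.

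KO effects were then compared across genes between kits, whose comparisons share no library. At 32 h the Zfp281 KO effect had a Pearson correlation of 0.27 (Spearman 0.4) with the Ehmt1 KO effect, 0.14 (0.11) with the Zic2 KO effect and 0.23 (0.33) with the double KO effect over 15467 genes, which are not independent replicates. Genes called higher in both Zfp281 KO and Ehmt1 KO at 32 h numbered 947, against 461 for independent lists, and genes lower in both 769 against 259.1. For the double KO these were 1166 against 653.1 and 956 against 402.5. At ESC the correlations were 0.02 (0.23), 0.05 (0.03) and -0.04 (0.17), with 528 genes higher (230.4) and 369 lower (122.7) in both Zfp281 KO and Ehmt1 KO, and 611 (327.6) and 407 (186.8) for the double KO. Leaving out single libraries moved the correlation with Ehmt1 KO from 0.17 to 0.54 at 32 h and from -0.07 to 0.44 at ESC, and that with the double KO from 0.13 to 0.52 and from -0.13 to 0.42. The higher ends came without the Zfp281_WT library of that stage and the lower ends without the line WT. With at least 5 CPM in both kits, the correlations were 0.56 (Ehmt1 KO) and 0.51 (double KO) at 32 h and 0.47 and 0.4 at ESC. For the WT time course the kits had a correlation of 0.75 (Spearman 0.75), with 1634 genes higher in both (506.3 for independent lists), 1595 lower in both (373.3) and 4 called in opposite directions.

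Within the polyA set, Ehmt1 KO and double KO effects had a correlation across 15667 genes of 0.94 at ESC and at 32 h. Their covariance was 2.156 at ESC and 1.698 at 32 h, against 0.13 and 0.103 for simulated unchanged groups with the same WT libraries, whose correlation was 0.51. Genes called higher in both numbered 2099 at ESC and 2127 at 32 h (482.9 and 506.4 for independent lists), and lower in both 1543 and 1493 (351.3 and 318.3). The covariance of Ehmt1 KO with Zic2 KO was 0.303 and 0.16 (simulated 0.127 and 0.102), and that of Zic2 KO with the double KO 0.373 and 0.224 (simulated 0.13 and 0.102), with correlations of 0.31 and 0.23, and 0.36 and 0.3. Simulated correlations of these pairs (0.49 to 0.51) were above those observed. So were their same-sign genes (66.7% to 67.1%, observed 56% to 63.1%), so an effect shared by most genes was not shown. Simulated groups had 0 shared calls on average. With each KO set against a different WT library of its stage, Ehmt1 KO and double KO had a correlation of 0.82 at ESC and 0.84 at 32 h.

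The transition as a whole was read from genes picked in the WT cells of the other kit, with at least a 2-fold change. In the ribo-depleted set, genes rising at 32 h (1666) rose by a mean log2 of 1.21 ± 0.22 in WT and 0.89 ± 0.04 in Zfp281 KO, which was 73.8% of WT. Genes falling (1221) changed by -1.28 ± 0.14 and -1.02 ± 0.04 (79.7%). By line, the values were 1.36 and -1.38 in WT and 1.05 and -1.18 in Zfp281_WT, against 0.86 and -1.05 in KO clone 1 and 0.92 and -1 in KO clone 2. In the polyA set, the 891 rising genes rose by 1.97 ± 0.08 in WT, 1.46 ± 0.21 in Ehmt1 KO (74.2%), 1.82 ± 0.02 in Zic2 KO (92.5%) and 1.11 ± 0.01 in the double KO (56.6%). The 612 falling genes changed by -2.11 ± 0.04 in WT, -1.39 ± 0.23 in Ehmt1 KO (65.7%), -1.94 ± 0.03 in Zic2 KO (91.9%) and -0.98 ± 0.11 in the double KO (46.3%). Values are mean ± SD of n = 2 lines, and the p of an exact permutation test, taken over both directions, was 0.33 for each genotype, the smallest that 2 against 2 lines can give.

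**Figure D3:**
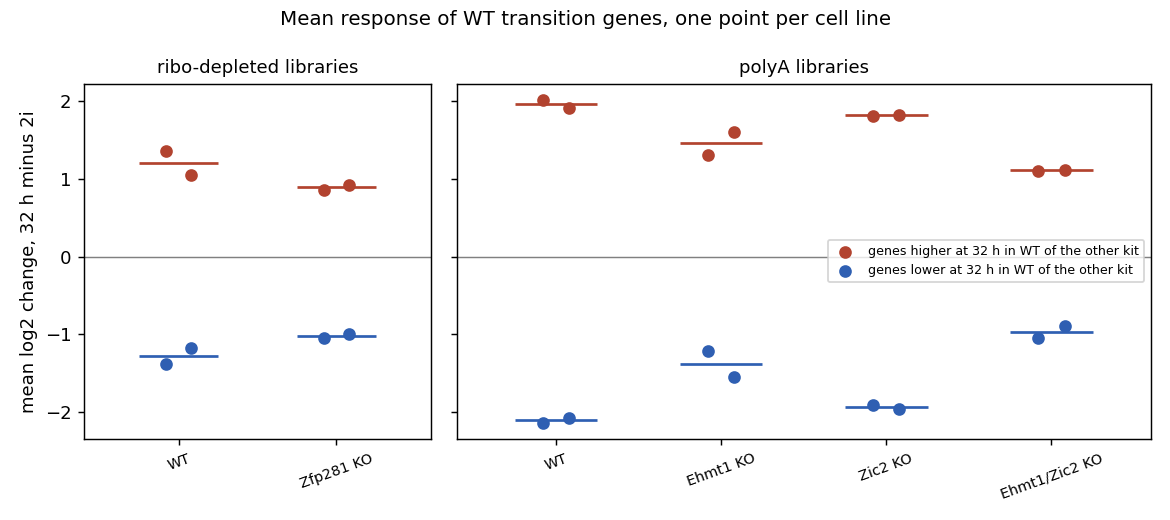
Mean log2 change from 2i to 32 h (y axis) of genes picked in the WT cells of the other kit, for genes higher (red) and lower (blue) at 32 h, with 1 point per cell line and a bar at the mean of 2 lines. The double KO has the polyA means nearest to 0, 1.11 and -0.98 against 1.97 and -2.11 in WT.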

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

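The tests of X-linked genes between lines, of olfactory receptor genes and of the Spearman correlation and the minimum of 5 CPM for genes not called over time were chosen after the result was seen. The results listed here are those in which a KO and WT cells responded differently to 2i withdrawal, by an interaction test with 2 lines per group.

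In Zfp281 KO, 787 genes responded differently. The log2 differences in response were 1.64 for Nr5a2, 1.45 for Nr0b1, 1.71 for Prdm14, 1.64 for Klf2 and 2.44 for Ap3b2, and -1.97 for Pim2, -1.07 for Fgf5, -1.97 for Etv4, -2.22 for Fst and -4.02 for Kif1a. Leaving out a single KO library took the count to between 62 and 143. In Ehmt1 KO, 291 genes responded differently (42 without WT replicate 2 at 32 h), with 1.66 for Esrrb, 1.41 for Zfp42, 2.29 for Prdm14, 1.41 for Nanog, 1.17 for Id3 and 3.65 for Spic, and -4.12 for Nefm, -6.02 for Gabra3, -3.83 for Cdx2 and -2.51 for Lrp2. In the double KO, 829 genes did (280 without WT replicate 1 at 32 h), with 2.76 for Esrrb, 2.67 for Klf4, 2.03 for Nanog, 2.58 for Prdm14, 2.81 for Lefty2 and 3.08 for Id3, and -3.19 for Pim2, -1.47 for Dnmt3b, -7.31 for Gabra3 and -3.73 for Lrp2.

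X-linked genes were higher in Zfp281 KO than in WT libraries. The WT lines also differed from each other, Zfp281_WT being lower, with a median log2 ratio to WT over X-linked genes of -0.25 at ESC, -0.23 at 16 h and -0.27 at 32 h, against 0.06, 0 and 0 for autosomal genes. A difference between lines in the number or activity of X chromosomes is therefore a candidate explanation for part of the shift. The KO clones were higher by 0.55, 0.46 and 0.36 against Zfp281_WT and by 0.35, 0.23 and 0.22 against WT at the 3 stages, so loss of Zfp281 cannot be told apart from line here, because each line has a single genotype.

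Counts in genes with none in any polyA library (silent genes) set the line Zfp281_WT apart at ESC and 32 h. If genomic DNA were the source, the excess could rise with exonic length. The Spearman correlation across silent genes was 0.45 at ESC and 0.43 at 32 h (0.01 in the line WT), between the limits of 0.2 and 0.5 set in advance, so genomic DNA stays open. Markers of neural, fibroblast and trophoblast cells exceeded silent genes per exonic kb by ratios of 2.33 and 3.54, on both sides of the limit of 3, and left another cell type undecided on that test. A count in 89.2% and 87% of olfactory receptor genes argues against RNA from another cell type as the whole source, since a cell type uses few of them.

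Zfp281 KO and Ehmt1 KO effects went together across genes at 32 h (r = 0.27). X-linked genes as the source are argued against, since r was 0.25 over 14874 genes without them. The test set in advance left a shared lag in the WT time course open, since Pearson's r was 0.12 (0.03 to 0.54 with a library left out) among 8247 genes not called over time, between limits of 0.1 and 0.2. The tests chosen afterwards gave a Spearman correlation of 0.3 (0.24 to 0.47) among them. The 4871 with at least 5 CPM in both kits gave r of 0.53 (0.46 to 0.56). Neither test decides, since genes not called may still change over time. Nor was a lag told apart from a shared effect among 7220 genes called over time (r = 0.5).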

How the results depend on the processing

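The fits without the line Zfp281_WT, those without X-linked genes, list tests without single libraries and leaving out or splitting libraries in the comparison of KO effects with each other were chosen after seeing the data. No named gene reversed under any alternative. With DESeq2's size factors all 18 counts of called genes stayed within 1.5 times, and so did the 4 Zfp281 KO counts without X-linked genes. Size factors moved the median of all genes by less than 0.1, and the share of higher calls by at most 8.9 points, which turned the excess in the ribo-depleted WT time course (57.7% to 48.8%). DESeq2 turned it there (49.2%), in the Zfp281 KO difference in response (46.9% to 55%), in Zic2 KO at 32 h (58.3% to 47.9%) and in the double KO against Ehmt1 KO (51.4% to 44.4%). The causes of the moves here were not tested, and some counts rose in fits with fewer degrees of freedom.

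With the line as a replicate block, the counts were 7525 (ribo-depleted WT time course), 2605 (Zfp281 KO difference in response), 1361 (Ehmt1 KO), 50 (Zic2 KO) and 2611 (double KO), and the block changed no call, estimated correlation included, beyond those given with the results. With only the groups compared they were 2298 (ribo-depleted WT time course), 132, 41 and 374 (Ehmt1, Zic2 and double KO differences in response), 207 and 1516 (Zic2 KO at ESC and 32 h), 3386 (double KO at ESC) and 0 (double KO against Ehmt1 KO). DESeq2 gave 616, 23 and 1334 (Ehmt1, Zic2 and double KO differences in response), 276 and 165 (Zic2 KO at ESC and 32 h), 261 (double KO against Ehmt1 KO) and 13 (additivity). No filter gave 94 and 48 (Zic2 KO) and 69 (double KO against Ehmt1 KO). Without the line Zfp281_WT, 5511 genes were called in Zfp281 KO at ESC and 2988 for its difference in response. Of 109 called list tests 10 were called with an estimated correlation. Fry called 84, of which 53 were shared. With each library left out in turn 62 of the 109 were always called, 47 were lost at least once and 5 turned direction at least once.

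Leaving out each library gave 3953 to 6086 genes (ribo-depleted WT) and 3499 to 5157 (polyA WT) over time, 539 to 6537, 2137 to 7008 and 2498 to 4944 (Zfp281 KO at ESC, 16 h and 32 h) and 62 to 1771 (difference in response). For Ehmt1 KO it gave 2590 to 3657, 2191 to 3732 and 42 to 295 (ESC, 32 h and difference in response), for Zic2 KO 0 to 214, 2 to 2 and 0 to 8, and for the double KO 3855 to 5835, 3745 to 4735 and 280 to 1334. The double KO gave 0 to 280 against Ehmt1 KO and 3131 to 4430 against Zic2 KO, and additivity 0 to 1. A library left alone in its group is assumed to vary like the other groups. The zeros are edgeR counts, with DESeq2 and unadjusted counts given in the report.

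Correlations of the Zfp281 KO effect ranged from -0.07 to 0.44, -0.03 to 0.1 and -0.13 to 0.42 at ESC (Ehmt1, Zic2 and double KO) and from 0.17 to 0.54, 0.08 to 0.15 and 0.13 to 0.52 at 32 h, and with at least 5 CPM were 0.47 and 0.4 at ESC and 0.56 and 0.51 at 32 h (Ehmt1 and double KO). Covariances at ESC and 32 h ranged from 0.237 to 0.606 and 0.085 to 0.366 (Ehmt1 with Zic2 KO), 2.038 to 2.616 and 1.555 to 2.041 (Ehmt1 with double KO), and 0.288 to 0.703 and 0.149 to 0.446 (Zic2 with double KO). With a different WT library for each KO they were 0.122 to 0.259, 1.802 to 2.25 and 0.201 to 0.355 over both stages. The mean response of transition genes with no fold minimum was -0.81 and 0.88 (ribo-depleted WT), -0.64 and 0.63 (Zfp281 KO), -1.09 and 0.93 (polyA WT), -0.72 and 0.67 (Ehmt1 KO), -0.98 and 0.86 (Zic2 KO) and -0.52 and 0.51 (double KO), as the added genes change less. With a prior count of 0.5 it was -2.17 and 2.06 (polyA WT), -1.06 and 0.97 (Zfp281 KO), -1.99 and 1.92 (Zic2 KO) and 1.2 (double KO, rising genes). Among named genes, leaving out a library kept 1208 results and ended 146 calls, only the groups compared kept 261 and ended 22, no filter kept 302 and ended 7, and the joint fit of the 16 h libraries kept 22 and ended 4.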
